A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

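The series holds 24 libraries, 2 biological replicates in each of 12 groups formed by assay (poly(A) mRNA or ribosome footprints), genotype (wild type or zuo1Δ) and condition (unstressed, H2O2 or heat). Per the labels' protocols, cells were grown in synthetic complete medium and sequenced on an Illumina platform. The deposited values are raw read counts per gene. The tools cutadapt, Bowtie2, HISAT2 and SAMtools and the build R64 are named per the submitters' processing notes, with no versions, roles or order. The counting tool, annotation and strand setting are not given in the sources used here, so reads of near-identical copies, overlapping genes and antisense genes cannot be told apart. Of 5211 genes, 5198 IDs matched the reference gene table, which gave the symbols. The 3 lines of the deposited table that had been emptied were left out.

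A gene was above 0 in all 12 libraries of a genotype or at 0 in all 12. The 5070 genes above 0 in both genotypes were used, and 87 at 0 throughout wild type and 54 at 0 throughout zuo1Δ were left out of the comparisons. Library totals ran from 7810893 to 122213415 counts for mRNA and from 1686930.0 to 15788345 for footprints. No molecular identifiers are named in the labels, so reads need not be independent molecules. Between replicates the SD of the log2 ratio across genes was 0.561 to 0.851 in mRNA and 0.32 to 0.498 in footprints, and the biological coefficient of variation was 0.318 and 0.169.

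Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The comparisons, lists, naming rule and most other settings were fixed before the data were examined. The edgeR quasi-likelihood test was fitted to all 12 libraries of an assay with TMM factors and the filterByExpr filter (minimum count 10, minimum total 15). A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The 9 contrasts were the genotype difference in each of 3 conditions, each stress against unstressed in each genotype, and the interaction of each stress with genotype. Translational efficiency was the footprint difference minus the mRNA difference in 1 model of all 24 libraries, which gives 27 results. SE is the absolute log2 fold change over the square root of the F statistic.

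For each contrast and assay the text names the 5 largest rises and 5 largest falls among genes that passed, at a mean of at least 10 CPM and, outside interactions, without overlap of the groups. It also names up to 4 members of each list described, those that passed with the largest change, made up with the smallest adjusted p. SSZ1, SSB1 and SSB2 are named for footprints in each genotype comparison, and ZUO1 and the strain's marker genes were left out of the top picks. Of 28 gene lists, 25 with at least 5 genes in both genotypes were tested with camera (preset correlation 0.01, prior count 2) and with an estimated correlation. Alpha-cell genes had 1 measured member, meiosis and sporulation genes 4 and mitochondrially encoded genes 0, so these were not tested.

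The other settings fixed in advance were RLE factors, library size alone, no low-count filter, DESeq2, a fit of only the groups compared, a replicate block, and leaving out each library in turn. Settings added after the data were seen were leaving out the 3 doubted libraries together, keeping genes at 0 in 1 genotype, and limma-voom on quantile-normalised mRNA counts. The tests were also run on simulated counts for the real genes, with 100 genes changed by 2-fold and 100 by 4-fold. For the unstressed genotype comparison over 5059 genes of footprints edgeR recovered 67 of 100 at 2-fold and 96 at 4-fold. In mRNA and efficiency (5070 genes each) it recovered 11 and 76, and 3 and 43. For the H2O2 interaction it recovered 15 and 78 in footprints (5058 genes), 0 and 14 in mRNA and 0 and 9 in efficiency. It called 14, 3 and 0 unchanged genes, and 13, 0 and 0 in the interaction.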

Results

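The series measured budding yeast of strain BY4741 and of a mutant of it without ZUO1, called zuo1Δ here. Zuo1 is the J-domain chaperone that works with Ssz1 and the Hsp70 Ssb at the ribosome exit tunnel. Cells in exponential growth were left unstressed, given 0.25 mM hydrogen peroxide (H2O2) for 30 min, or shifted to 37 °C for 45 min. Poly(A) mRNA and ribosome footprints, the mRNA fragments that ribosomes protect from nuclease, were sequenced from each of the 2 genotypes and 3 conditions. There were 2 biological replicates in each of 12 groups, 24 libraries in all, with totals as given under processing. ZUO1 (YGR285C) was listed at 0 in all 12 zuo1Δ libraries. In wild type its mRNA stood at 583 ± 143 CPM, counts scaled by library total and TMM factor (mean ± SD, n = 2), without stress, 336 ± 72.7 after H2O2 and 441 ± 86.8 after heat, while library totals alone, which turn the order, gave 253, 335 and 263. In a fit within wild type the mRNA did not pass after H2O2 (-0.74, adjusted p = 0.35) or heat (-0.38, adjusted p = 0.602). Its wild-type footprints stood at 1401 ± 0.823, 799.6 ± 3.12 and 1072 ± 3.16 CPM in that order.

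In 3 stressed zuo1Δ libraries the markers of the stress on the label stood no higher than in the highest unstressed library of the assay, and directions drawn from these carry that limit. The rule was set after the values were seen. The markers were the 78 genes among the 100 largest wild-type footprint rises after H2O2 that were not among the 100 largest after heat, and the 78 for heat alone. The median log2 level of the H2O2 markers, relative to the unstressed libraries of the same assay, was 2.22 and 1.94 in the wild-type H2O2 mRNA replicates, and that of the heat markers 0.91 and 0.76 in the wild-type heat mRNA replicates. In zuo1Δ mRNA the H2O2 markers stood at 1.22 in the library labelled H2O2 replicate 1, 0.35 in the library labelled H2O2 replicate 2, 1.00 in the library labelled heat replicate 1 and 0.06 in heat replicate 2. The heat markers stood at -0.19, 0.63, 0.13 and 0.44 in the same 4 libraries. The unstressed zuo1Δ mRNA replicates also lay apart on the H2O2 markers, at 0.43 and -0.46, and the highest unstressed library on the heat markers stood at 0.15. In footprints, the H2O2 markers stood at 0.11 in the zuo1Δ library labelled H2O2 replicate 1 and 1.60 in replicate 2, against 0.68 and 0.00 in the unstressed zuo1Δ libraries and 2.54 and 2.40 in wild type after H2O2. The 3 doubted libraries below are zuo1Δ mRNA labelled H2O2 replicate 2, zuo1Δ mRNA labelled heat replicate 1 and zuo1Δ footprints labelled H2O2 replicate 1. The mRNA libraries also differed in composition, since the 50 highest genes took 27.2% to 61.7% of the counts in wild-type mRNA, 19% to 33% in zuo1Δ mRNA and 25.2% to 35.1% in footprints.

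**Figure D1:**
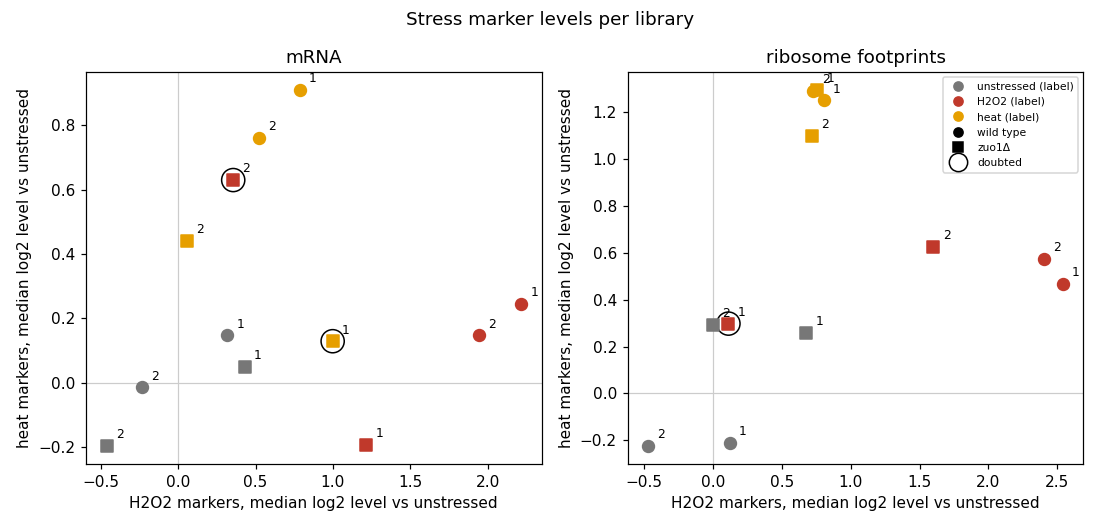
Median log2 level of the H2O2 markers (x axis) against that of the heat markers (y axis), relative to the unstressed libraries of the same assay, for mRNA (left panel) and footprints (right panel). Each point is 1 library, coloured by the condition on its label and marked by genotype, with the replicate number beside it, and the 3 doubted zuo1Δ libraries are ringed.

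The first comparison asked what loss of Zuo1 does without stress. Footprints on PHO5, PHO11 and PHO12 were lower in zuo1Δ and those on GSC2, ENA1 and PHO87 were higher (edgeR, 2 libraries per group). Values in parentheses are log2 fold changes ± SE, and medians of lists are of log2 fold changes. The acid phosphatases PHO5 (-3.01 ± 0.28, adjusted p = 0.000117), PHO11 (-3.36 ± 0.56, adjusted p = 0.00553) and PHO12 (-3.00 ± 0.35, adjusted p = 0.000635) fell, with PHO11 and PHO12 uncertain as near-identical copies. PHO5 went from 375 ± 7.93 CPM (mean ± SD, n = 2) in wild type to 46.3 ± 13.3 CPM. Among 15 genes of the phosphate regulon, 12 fell and 0 rose (13 and 1 adjusted over the list alone). Their median was -1.29 (camera adjusted p = 9.7e-14, and adjusted p = 0.0117 with an estimated correlation). The inducible glucan synthase GSC2 (3.45 ± 0.19, adjusted p = 2.4e-06), the sodium pump ENA1 (2.92 ± 0.40, adjusted p = 0.00166), the phosphate transporter PHO87 (2.24 ± 0.22, adjusted p = 0.000159), the kinase KIN82 (2.24 ± 0.53, adjusted p = 0.0328) and DIA1 (3.48 ± 0.35, adjusted p = 0.000216) rose most. Large falls also met IMP dehydrogenase IMD2 (-3.09 ± 0.19, adjusted p = 3.34e-06) and YOR309C (-3.54 ± 0.46, adjusted p = 0.0013), an ID with no entry in the gene table. For cell wall integrity genes, 6 rose and 0 fell (12 and 3 over the list alone) of 28 measured. Their median was 0.04 (camera adjusted p = 0.0415, and adjusted p = 0.525 with an estimated correlation). The camera adjusted p of this list became 0.078 without the doubted libraries, 0.124 without wild-type unstressed replicate 2 and 0.0582 without zuo1Δ unstressed replicate 2, within 0.0115 to 0.525 over all settings. Examples were SRL3 (2.07 ± 0.53, adjusted p = 0.0456) and NCW2 (1.85 ± 0.22, adjusted p = 0.00069).

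More ribosomal protein, amino acid and glycolysis genes fell than rose in unstressed zuo1Δ footprints, and more respiration genes rose than fell. Of the 136 cytosolic ribosomal protein genes measured, 35 fell and 2 rose (62 and 3 over the list alone). The median was -0.39 (camera adjusted p = 4.23e-16, and adjusted p = 0.462 with an estimated correlation). Examples were RPS12 (-1.22 ± 0.21, adjusted p = 0.00793) and RPL8A (-1.21 ± 0.17, adjusted p = 0.00205), while RPS9A (1.20 ± 0.14, adjusted p = 0.000737) rose, and paralogous copies make single members uncertain. Amino acid biosynthesis genes (58 measured) had a median of -0.38 (camera adjusted p = 5.18e-12, and adjusted p = 0.0214 with an estimated correlation). Among these, 14 fell and 0 rose (24 and 0 over the list alone). They included isopropylmalate isomerase LEU1 (-1.74 ± 0.15, adjusted p = 9.18e-05) and the histidine enzyme HIS4 (-1.31 ± 0.27, adjusted p = 0.0147). Of 27 glycolysis and fermentation genes, 9 fell and 0 rose (13 and 0 over the list alone). The median was -0.41 (camera adjusted p = 1.07e-06, and adjusted p = 0.225 with an estimated correlation). Among them was hexokinase HXK2 (-0.97 ± 0.14, adjusted p = 0.00206). Among 48 respiration genes, 12 rose and 0 fell (19 and 1 over the list alone). Their median was 0.43 (camera adjusted p = 3.92e-09, and adjusted p = 0.323 with an estimated correlation). Examples were the ATP synthase subunit ATP17 (1.44 ± 0.23, adjusted p = 0.00395) and the NADH dehydrogenase NDE1 (1.19 ± 0.15, adjusted p = 0.0013).

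Footprints on the partners of Zuo1 did not pass the test without stress, at SSZ1 (-0.05 ± 0.14, adjusted p = 0.892, 0.19 with library size alone), SSB1 (-0.36 ± 0.17, adjusted p = 0.27) and SSB2 (-0.26 ± 0.15, adjusted p = 0.37), the last 2 near-identical copies. SSB1 passed at -0.40 without the doubted libraries and -0.37 in a fit of only the groups compared. For Pdr1 drug resistance genes, 5 fell and 1 rose (6 and 1 over the list alone) of 16 measured. Their median was -0.16 (0.08 with library size alone, the opposite direction) (camera adjusted p = 0.0425, and adjusted p = 0.462 with an estimated correlation). For this list camera gave adjusted p = 0.0541 with RLE factors, 0.0668 without the doubted libraries, 0.229 without wild-type unstressed replicate 1 and 0.0576 without zuo1Δ unstressed replicate 2, in a range of 0.0122 to 0.462 over all settings. The fallers included the transporters PDR15 (-2.68 ± 0.41, adjusted p = 0.00332) and PDR12 (-2.24 ± 0.27, adjusted p = 0.000764). Of the 25 endoplasmic reticulum folding genes measured, 4 fell and 0 rose (5 and 1 over the list alone). The median was -0.22 (0.02 with library size alone, the opposite direction) (camera adjusted p = 0.00787, and adjusted p = 0.225 with an estimated correlation). The Hsp70 KAR2 (-1.06 ± 0.25, adjusted p = 0.0302) was among them. In all, 244 of 5064 genes passed, 90 higher and 154 lower. Library size alone split the calls into 402 higher and 86 lower, with the median of all genes moved by 0.24. The count was 1.0e+02 without wild-type unstressed replicate 1, 71 without wild-type unstressed replicate 2, 86 without zuo1Δ unstressed replicate 1 and 1.0e+02 without zuo1Δ unstressed replicate 2. Of the 23 named genes that passed, 18, 19, 19 and 18 kept their call in that order. The 2 counts written 1.0e+02 are rounded to 2 digits.

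In mRNA, 14 of 5070 genes passed without stress, 5 higher and 9 lower, while DESeq2 called 610 and a replicate block 472. An edgeR fit of only these 2 groups called 0, with 801 genes at an unadjusted p under 0.05. The lowest were IMD2 (-4.65 ± 0.46, adjusted p = 0.0005), PHO12 (-3.83 ± 0.44, adjusted p = 0.00117) and PHO11 (-3.31 ± 0.38, adjusted p = 0.00117), the phosphate-starvation protein SPL2 (-3.35 ± 0.63, adjusted p = 0.0476) and the permease FCY21 (-2.77 ± 0.49, adjusted p = 0.0465). The highest were the cytochrome bc1 subunit QCR6 (2.63 ± 0.46, adjusted p = 0.0457), IGO1 (2.15 ± 0.39, adjusted p = 0.0465), RNA15 (2.12 ± 0.39, adjusted p = 0.0465) and YOR385W (1.84 ± 0.31, adjusted p = 0.0457) and the calmodulin kinase CMK2 (1.75 ± 0.30, adjusted p = 0.0457). Cytosolic ribosomal protein genes (136 measured) had a median of -1.75 (camera adjusted p = 2.27e-40, and adjusted p = 0.354 with an estimated correlation). Among these, 1 fell and 0 rose (110 and 1 over the list alone). The split with library size alone was 2984 higher and 38 lower, at a shift of 1.51 in the median of all genes. The count was 8 without wild-type unstressed replicate 1, 5 without wild-type unstressed replicate 2, 515 without zuo1Δ unstressed replicate 1 and 4 without zuo1Δ unstressed replicate 2. Among the 10 named genes that passed, 3, 4, 10 and 3 kept their call in that order. Translational efficiency, the footprint difference minus the mRNA difference in 1 model, passed for 2 genes, the potassium transporter TRK1 (-2.42 ± 0.38, adjusted p = 0.02) and YOR309C (-4.67 ± 0.77, adjusted p = 0.02), the latter named after its value was seen. DESeq2 called 133, library size alone 826 and a fit of only these groups 0 for efficiency, and leaving out single libraries gave 1 without mRNA wild-type unstressed replicate 1, 0 without mRNA wild-type unstressed replicate 2, 399 without mRNA zuo1Δ unstressed replicate 1, 0 without mRNA zuo1Δ unstressed replicate 2, 1 without footprint wild-type unstressed replicate 1, 0 without footprint wild-type unstressed replicate 2, 0 without footprint zuo1Δ unstressed replicate 1 and 0 without footprint zuo1Δ unstressed replicate 2.

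The next comparison asked how wild-type cells respond to H2O2. More antioxidant, general stress and proteasome genes rose than fell in footprints, and more ribosomal protein and translation factor genes fell than rose. The peroxiredoxin TSA2 (7.43 ± 1.62, adjusted p = 0.0093), OSI1 (7.04 ± 1.81, adjusted p = 0.0197), the glutathione transferase GTT2 (6.33 ± 1.33, adjusted p = 0.00816), sulfiredoxin SRX1 (5.70 ± 1.39, adjusted p = 0.0152) and YMR090W (5.66 ± 1.26, adjusted p = 0.01) had the largest named rises (edgeR, n = 2 libraries per group). TSA2 footprints went from 16.4 ± 1.23 CPM (mean ± SD, n = 2) to 2840.0 ± 112 CPM. Glutamate synthase GLT1 (-2.48 ± 0.27, adjusted p = 0.000695), YOR309C (-2.34 ± 0.44, adjusted p = 0.00509), the branched-chain amino acid enzyme ILV3 (-1.84 ± 0.20, adjusted p = 0.000677), PHO5 (-1.76 ± 0.27, adjusted p = 0.00225) and the iron transporter FET4 (-1.75 ± 0.35, adjusted p = 0.00696) fell most. Of 31 Yap1 and Skn7 antioxidant genes, 21 rose and 0 fell (25 and 0 over the list alone). The median was 1.19 (camera adjusted p = 3.53e-09, and adjusted p = 0.388 with an estimated correlation). Among 42 Msn2 and Msn4 general stress genes, 30 rose and 0 fell (35 and 1 over the list alone). Their median was 2.02 (camera adjusted p = 9.91e-13, and adjusted p = 0.319 with an estimated correlation). They included MSC1 (4.12 ± 0.74, adjusted p = 0.00433) and the transaldolase NQM1 (4.10 ± 0.72, adjusted p = 0.0041). For proteasome genes, 28 rose and 0 fell (35 and 0 over the list alone) of 44 measured. Their median was 0.66 (camera adjusted p = 2.44e-11, and adjusted p = 0.319 with an estimated correlation). Polyubiquitin UBI4 (2.68 ± 0.41, adjusted p = 0.00234) led that list.

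Of the 136 cytosolic ribosomal protein genes measured, 94 fell and 0 rose (118 and 0 over the list alone). The median was -0.72 (camera adjusted p = 4.45e-35, and adjusted p = 0.294 with an estimated correlation). Translation factors (40 measured) had a median of -0.56 (camera adjusted p = 8.65e-13, and adjusted p = 0.294 with an estimated correlation). Among these, 25 fell and 0 rose (28 and 0 over the list alone). The elongation factor YEF3 (-1.33 ± 0.17, adjusted p = 0.00177) was among them. Of 104 ribosome biogenesis genes, 24 fell and 0 rose (28 and 0 over the list alone). The median was -0.58 (camera adjusted p = 6.66e-15, and adjusted p = 0.388 with an estimated correlation). Examples were the rRNA processing factor RRP5 (-1.44 ± 0.22, adjusted p = 0.00234) and the RNA polymerase I subunit RPA190 (-1.28 ± 0.18, adjusted p = 0.00209). Among 11 chaperones at the ribosome, 4 fell and 0 rose (8 and 0 over the list alone). Their median was -0.49 (camera adjusted p = 0.00108, and adjusted p = 0.294 with an estimated correlation). The fallers included SSB1 (-1.05 ± 0.17, adjusted p = 0.00341), SSB2 (-0.94 ± 0.15, adjusted p = 0.00274) and SSZ1 (-0.79 ± 0.15, adjusted p = 0.00464). For iron regulon genes, 9 rose and 2 fell (12 and 2 over the list alone) of 24 measured. Their median was 0.48 (camera adjusted p = 0.00752, and adjusted p = 0.294 with an estimated correlation). The haem oxygenase HMX1 (2.67 ± 0.43, adjusted p = 0.00293) rose and the iron reductase FRE4 (-1.82 ± 0.57, adjusted p = 0.0453) fell. Of the 71 mitochondrial ribosomal protein genes measured, 7 rose and 0 fell (3 and 0 over the list alone). The median was 0.49 (camera adjusted p = 1.09e-07, and adjusted p = 0.294 with an estimated correlation). In all, 919 genes passed, 474 higher and 445 lower. Scaling by library size alone gave 926 higher and 254 lower and shifted the median of all genes by 0.21. The count was 654 without wild-type unstressed replicate 1, 233 without wild-type unstressed replicate 2, 299 without wild-type H2O2 replicate 1 and 346 without wild-type H2O2 replicate 2. Of the 21 named genes that passed, 16, 11, 17 and 19 kept their call in that order.

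In wild-type mRNA, 135 genes passed after H2O2, 73 higher and 62 lower, and DESeq2 called 596. Transcripts of TSA2 (7.86 ± 1.86, adjusted p = 0.0459), SRX1 (5.45 ± 1.22, adjusted p = 0.0436), YMR090W (4.91 ± 1.08, adjusted p = 0.0436), GTT2 (4.59 ± 0.86, adjusted p = 0.0286) and SOL4 (4.35 ± 0.65, adjusted p = 0.0159) rose most. The ribosomal protein genes RPL39 (-5.10 ± 0.89, adjusted p = 0.0214), RPL29 (-3.67 ± 0.72, adjusted p = 0.0326) and RPS30B (-2.99 ± 0.42, adjusted p = 0.0149), GLT1 (-3.10 ± 0.62, adjusted p = 0.0326) and the elongation factor ANB1 (-2.96 ± 0.62, adjusted p = 0.0414) fell most. Cytosolic ribosomal protein genes (136 measured) had a median of -1.96 (camera adjusted p = 4.23e-56, and adjusted p = 0.161 with an estimated correlation). Among these, 39 fell and 0 rose (133 and 0 over the list alone). Of 42 Msn2 and Msn4 general stress genes, 11 rose and 0 fell (21 and 0 over the list alone). The median was 1.33 (camera adjusted p = 2.99e-14, and adjusted p = 0.232 with an estimated correlation). Library size alone split the calls into 1560 higher and 21 lower, with the median of all genes moved by 1.22. The count was 67 without wild-type unstressed replicate 1, 0 without wild-type unstressed replicate 2, 1 without wild-type H2O2 replicate 1 and 0 without wild-type H2O2 replicate 2. Among the 10 named genes that passed, 5, 0, 0 and 0 kept their call in that order. For translational efficiency no gene passed the edgeR test, while 499 had an unadjusted p under 0.05 and DESeq2 called 20.

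Heat shock in wild type was compared with the unstressed state to ask how cells respond to 37 °C. In footprints more ribosomal protein and translation factor genes fell than rose, and more cell wall genes rose than fell. HBT1 (5.27 ± 0.76, adjusted p = 0.00135), the membrane-protecting HSP12 (4.72 ± 0.86, adjusted p = 0.00536), YOR338W (4.54 ± 0.93, adjusted p = 0.00973), the transaldolase NQM1 (4.03 ± 0.73, adjusted p = 0.00518) and the membrane protein HSP30 (3.77 ± 1.04, adjusted p = 0.0404) rose most (n = 2 libraries per group, edgeR). The sorting factor BTN2 (-2.43 ± 0.57, adjusted p = 0.0207), flavohaemoglobin YHB1 (-2.34 ± 0.20, adjusted p = 9.77e-05), the exporter QDR2 (-2.31 ± 0.21, adjusted p = 0.000129), glutamate dehydrogenase GDH1 (-2.13 ± 0.18, adjusted p = 7.89e-05) and PHO11 (-2.10 ± 0.55, adjusted p = 0.033) fell most. Among 27 cytosolic chaperones of the Hsf1 type, 7 rose and 2 fell (11 and 4 over the list alone). Their median was 0.43 (camera adjusted p = 0.102, and adjusted p = 0.712 with an estimated correlation). For this list camera gave adjusted p = 0.0148 without wild-type unstressed replicate 1 and 0.0125 without wild-type heat replicate 2, in a range of 0.0125 to 0.712 over all settings. The small heat shock protein HSP26 (3.38 ± 0.58, adjusted p = 0.00402) and the Hsp70 SSA4 (3.36 ± 0.60, adjusted p = 0.00486) were among the risers. For Msn2 and Msn4 general stress genes, 6 rose and 0 fell (7 and 1 over the list alone) of 42 measured. Their median was 0.94 (camera adjusted p = 0.000248, and adjusted p = 0.558 with an estimated correlation). The camera adjusted p of this list became 0.0599 without wild-type unstressed replicate 2, within 7.45e-10 to 0.558 over all settings. Of the 28 cell wall integrity genes measured, 10 rose and 2 fell (11 and 4 over the list alone). The median was 0.26 (camera adjusted p = 0.00807, and adjusted p = 0.457 with an estimated correlation). They included GSC2 (3.55 ± 0.19, adjusted p = 1.8e-06) and SRL3 (2.59 ± 0.53, adjusted p = 0.00973).

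Cytosolic ribosomal protein genes (136 measured) had a median of -0.84 (camera adjusted p = 5.76e-48, and adjusted p = 0.216 with an estimated correlation). Among these, 101 fell and 0 rose (120 and 1 over the list alone). Of 40 translation factors, 18 fell and 0 rose (26 and 0 over the list alone). The median was -0.49 (camera adjusted p = 5.54e-13, and adjusted p = 0.216 with an estimated correlation). Elongation factor 2 is encoded by the near-identical EFT1 (-2.03 ± 0.33, adjusted p = 0.00267) and EFT2 (-1.82 ± 0.28, adjusted p = 0.00224). Among 11 chaperones at the ribosome, 4 fell and 0 rose (7 and 1 over the list alone). Their median was -0.63 (camera adjusted p = 0.00668, and adjusted p = 0.377 with an estimated correlation). The fallers included SSB1 (-1.48 ± 0.18, adjusted p = 0.000746), SSB2 (-1.17 ± 0.15, adjusted p = 0.000759) and SSZ1 (-0.77 ± 0.15, adjusted p = 0.00674). For a-cell genes, 4 fell and 0 rose (4 and 0 over the list alone) of 7 measured. Their median was -0.69 (camera adjusted p = 0.000248, and adjusted p = 0.216 with an estimated correlation). The pheromone receptor STE2 (-1.37 ± 0.18, adjusted p = 0.000823) was among them. In all, 497 genes passed after heat in wild type, 179 higher and 318 lower. The split with library size alone was 655 higher and 164 lower, at a shift of 0.26 in the median of all genes. The count was 239 without wild-type unstressed replicate 1, 197 without wild-type unstressed replicate 2, 227 without wild-type heat replicate 1 and 133 without wild-type heat replicate 2. Of the 20 named genes that passed, 16, 12, 17 and 13 kept their call in that order.

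In wild-type mRNA 35 genes passed after heat, 20 higher and 15 lower, and DESeq2 called 646. The risers included HSP12 (5.20 ± 0.70, adjusted p = 0.0209), YOR338W (3.31 ± 0.58, adjusted p = 0.0335), HSP26 (3.07 ± 0.50, adjusted p = 0.0279), SSA4 (2.62 ± 0.49, adjusted p = 0.0388) and LOA1 (2.54 ± 0.46, adjusted p = 0.0335). The fallers included LEU1 (-3.60 ± 0.53, adjusted p = 0.0216), YHB1 (-3.42 ± 0.60, adjusted p = 0.0335), RPS1A (-2.76 ± 0.56, adjusted p = 0.0461), RPS30B (-2.67 ± 0.41, adjusted p = 0.0216) and RPL20A (-2.58 ± 0.53, adjusted p = 0.0461). Of the 136 cytosolic ribosomal protein genes measured, 6 fell and 1 rose (83 and 1 over the list alone). The median was -1.54 (camera adjusted p = 5.15e-35, and adjusted p = 0.37 with an estimated correlation). Scaling by library size alone gave 44 higher and 9 lower and shifted the median of all genes by 0.48. The count was 663 without wild-type unstressed replicate 1, 0 without wild-type unstressed replicate 2, 0 without wild-type heat replicate 1 and 2 without wild-type heat replicate 2. Among the 10 named genes that passed, 10, 0, 0 and 2 kept their call in that order. Translational efficiency passed for 5 genes. The transcription factor GCN4 (4.61 ± 0.83, adjusted p = 0.0364), HBT1 (4.30 ± 0.81, adjusted p = 0.0406) and YAT2 (3.61 ± 0.65, adjusted p = 0.0364) were higher, the last named after its value was seen, and LOA1 (-3.54 ± 0.54, adjusted p = 0.014) and VPS62 (-2.42 ± 0.44, adjusted p = 0.0364) were lower. Library size alone kept only LOA1, the others standing at 4.59, 4.14, 3.63 and -2.51 in that order. A fit of only the groups compared called 2, both named. DESeq2 called 18 for efficiency, and leaving out single libraries gave 309 without mRNA wild-type unstressed replicate 1, 0 without mRNA wild-type unstressed replicate 2, 0 without mRNA wild-type heat replicate 1, 1 without mRNA wild-type heat replicate 2, 0 without footprint wild-type unstressed replicate 1, 0 without footprint wild-type unstressed replicate 2, 0 without footprint wild-type heat replicate 1 and 0 without footprint wild-type heat replicate 2.

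H2O2 was compared with the unstressed state in zuo1Δ to ask how the mutant responds, with 1 of the 2 libraries labelled H2O2 doubted in each assay. In footprints no gene passed the edgeR test, while 444 had an unadjusted p under 0.05 and DESeq2 called 27. Values for the antioxidant genes that led in wild type were TSA2 (4.82 ± 1.35, adjusted p = 0.391) and GTT2 (2.78 ± 0.80, adjusted p = 0.391) here (n = 2 libraries per group, edgeR). TSA2 passed at 4.81 with DESeq2, 5.85 without zuo1Δ H2O2 replicate 1 and -1.61 without zuo1Δ H2O2 replicate 2. GTT2 passed at 3.76 without zuo1Δ H2O2 replicate 1. TSA2 footprints stood at 48.8 ± 1.14 CPM (mean ± SD) without stress and 1382 ± 1931 CPM in the libraries labelled H2O2. Without the doubted libraries 184 genes passed, 119 higher and 65 lower. Glycolysis and fermentation genes (27 measured) had a median of -0.33 (camera adjusted p = 2.11e-06, and adjusted p = 0.505 with an estimated correlation). Among these, 0 fell and 0 rose (10 and 0 over the list alone). Of 136 cytosolic ribosomal protein genes, 0 fell and 0 rose (7 and 0 over the list alone). The median was -0.19 (camera adjusted p = 7.75e-11, and adjusted p = 0.682 with an estimated correlation). The camera adjusted p of this list became 0.37 without zuo1Δ H2O2 replicate 2, within 2.26e-20 to 0.682 over all settings. ADH1 (-0.68 ± 0.14, adjusted p = 0.388) and CDC19 (-0.57 ± 0.13, adjusted p = 0.391) were members of the first list. ADH1 passed at -0.69 with DESeq2 and -0.82 without zuo1Δ H2O2 replicate 1. CDC19 passed at -0.59 with DESeq2 and -0.67 without zuo1Δ H2O2 replicate 1. Leaving out single footprint libraries gave 184 without zuo1Δ H2O2 replicate 1, 1 without zuo1Δ H2O2 replicate 2 and 0 without each other library.

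In zuo1Δ mRNA 2 genes passed after H2O2, the small heat shock proteins HSP12 (4.88 ± 0.69, adjusted p = 0.0174) and HSP26 (3.69 ± 0.51, adjusted p = 0.0174), 481 had an unadjusted p under 0.05. DESeq2, whose own filter kept 745 genes, called 87, 8 higher and 79 lower, HSP12 and HSP26 not among them. Library size alone split the calls into 2 higher and 0 lower, with the median of all genes moved by 0.43. The count was 2 without zuo1Δ unstressed replicate 1, 0 without zuo1Δ unstressed replicate 2, 4 without zuo1Δ H2O2 replicate 1 and 0 without zuo1Δ H2O2 replicate 2. Of the 2 named genes that passed, 2, 0, 2 and 0 kept their call in that order. Without the doubted libraries 5 genes passed, and HSP12 and HSP26 did not. For translational efficiency no gene passed the edgeR test and DESeq2 called 0. An unadjusted p under 0.05 met 222 of 5070 genes, below the share of 0.05 that unchanged genes would give.

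Heat shock in zuo1Δ was compared with the unstressed mutant, with both heat footprint libraries following their labels. More phosphate genes rose than fell in footprints, and more histone and ribosomal protein genes fell than rose. GPG1 (4.63 ± 0.64, adjusted p = 0.00221), HSP12 (3.64 ± 0.76, adjusted p = 0.0134), the riboflavin transporter MCH5 (3.50 ± 0.55, adjusted p = 0.00385), the pentose phosphate enzyme GND2 (3.43 ± 0.92, adjusted p = 0.0323) and STP4 (3.31 ± 0.69, adjusted p = 0.0134) rose most (n = 2 libraries per group, edgeR). The vacuolar transporter VMR1 (-2.73 ± 0.29, adjusted p = 0.000543), the endonuclease HO (-2.66 ± 0.29, adjusted p = 0.000543), the siderophore transporter SIT1 (-2.49 ± 0.33, adjusted p = 0.00202), the coactivator MBF1 (-2.45 ± 0.23, adjusted p = 0.000226) and histone HTA2 (-2.23 ± 0.31, adjusted p = 0.00221) fell most. Among 15 genes of the phosphate regulon, 8 rose and 0 fell (11 and 0 over the list alone). Their median was 0.78 (camera adjusted p = 3.07e-07, and adjusted p = 0.0703 with an estimated correlation). PHO5 went from 46.3 ± 13.3 CPM (mean ± SD, n = 2) to 421 ± 124 CPM, and the rise passed for PHO5 (3.17 ± 0.28, adjusted p = 0.000226). For histone genes, 9 fell and 0 rose (10 and 0 over the list alone) of 10 measured. Their median was -1.44 (camera adjusted p = 1.05e-08, and adjusted p = 0.297 with an estimated correlation). Reads of near-identical histone copies may be shared, so single members are uncertain. Of the 136 cytosolic ribosomal protein genes measured, 50 fell and 2 rose (76 and 4 over the list alone). The median was -0.48 (camera adjusted p = 1.72e-14, and adjusted p = 0.564 with an estimated correlation).

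Ribosome stalling and quality control genes (29 measured) had a median of 0.05 (camera adjusted p = 0.335, and adjusted p = 0.665 with an estimated correlation, the test pointing down). Among these, 4 fell and 0 rose (4 and 0 over the list alone). They included RQC1 (-0.84 ± 0.15, adjusted p = 0.006) and the ribosomal scaffold ASC1 (-0.81 ± 0.14, adjusted p = 0.00564). In all, 601 genes passed after heat in zuo1Δ, 284 higher and 317 lower. The split with library size alone was 512 higher and 159 lower, at a shift of 0.16 in the median of all genes. The count was 142 without zuo1Δ unstressed replicate 1, 329 without zuo1Δ unstressed replicate 2, 214 without zuo1Δ heat replicate 1 and 369 without zuo1Δ heat replicate 2. Among the 15 named genes that passed, 10, 11, 13 and 13 kept their call in that order. In mRNA no gene passed the edgeR test, while 517 had an unadjusted p under 0.05, with 1 of the 2 heat libraries doubted. DESeq2 called 66 in mRNA, of the 352 genes that its own filter kept. For efficiency no gene passed the edgeR test, while 403 had an unadjusted p under 0.05 and DESeq2 called 0, and leaving out single libraries gave 47 without mRNA zuo1Δ unstressed replicate 2 and 0 without each other library.

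The genotypes were compared after H2O2 to ask how loss of Zuo1 alters the stressed state, with 1 zuo1Δ library doubted in each assay. More ribosome biogenesis genes were higher than lower in zuo1Δ footprints, and more general stress, phosphate and glycolysis genes were lower than higher. GSC2 (3.35 ± 0.19, adjusted p = 1.5e-06), DIA1 (3.08 ± 0.29, adjusted p = 0.000231) and YOR338W (2.83 ± 0.62, adjusted p = 0.0116), the riboflavin transporter MCH5 (2.53 ± 0.57, adjusted p = 0.0127) and the sodium-phosphate cotransporter PHO89 (2.25 ± 0.26, adjusted p = 0.000551) were highest (n = 2 libraries per group, edgeR). PHO11 (-4.11 ± 0.58, adjusted p = 0.00179) and RGI1 (-3.94 ± 0.71, adjusted p = 0.0053), the ABC transporter PDR15 (-3.44 ± 0.41, adjusted p = 0.000671), PHO12 (-3.38 ± 0.35, adjusted p = 0.000418) and the protease YPS6 (-3.35 ± 0.67, adjusted p = 0.00809) were lowest. Of 104 ribosome biogenesis genes, 80 rose and 0 fell (100 and 0 over the list alone). The median was 0.89 (camera adjusted p = 7.26e-29, and adjusted p = 0.47 with an estimated correlation). Among 42 Msn2 and Msn4 general stress genes, 16 fell and 0 rose (23 and 0 over the list alone). Their median was -1.13 (camera adjusted p = 6.42e-08, and adjusted p = 0.49 with an estimated correlation). Phosphoglucomutase PGM2 (-2.71 ± 0.76, adjusted p = 0.0287) was among them. For genes of the phosphate regulon, 12 fell and 1 rose (13 and 1 over the list alone) of 15 measured. Their median was -0.88 (camera adjusted p = 4.39e-07, and adjusted p = 0.078 with an estimated correlation). Of the 27 glycolysis and fermentation genes measured, 13 fell and 1 rose (17 and 1 over the list alone). The median was -0.62 (camera adjusted p = 1.88e-06, and adjusted p = 0.295 with an estimated correlation).

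Yap1 and Skn7 antioxidant genes (31 measured) had a median of -0.86 (camera adjusted p = 4.52e-06, and adjusted p = 0.49 with an estimated correlation). Among these, 7 fell and 0 rose (10 and 0 over the list alone). For this list camera gave adjusted p = 0.0891 without the doubted libraries and 0.0891 without zuo1Δ H2O2 replicate 1, in a range of 4.4e-21 to 0.49 over all settings. The glutaredoxin GRX2 (-1.36 ± 0.31, adjusted p = 0.0133) was among them. Partners of Zuo1 did not pass after H2O2, at SSZ1 (0.38 ± 0.14, adjusted p = 0.0854), SSB1 (0.15 ± 0.17, adjusted p = 0.563) and SSB2 (0.36 ± 0.15, adjusted p = 0.104). SSZ1 passed at 0.54 with library size alone and 0.58 without zuo1Δ H2O2 replicate 2. SSB1 passed at 0.43 without zuo1Δ H2O2 replicate 2. SSB2 passed at 0.52 with library size alone and 0.55 without zuo1Δ H2O2 replicate 2. In all, 963 genes passed, 473 higher and 490 lower, and 415 passed without the doubted libraries, 250 higher and 165 lower. Scaling by library size alone gave 815 higher and 323 lower and shifted the median of all genes by 0.16. The count was 157 without wild-type H2O2 replicate 1, 206 without wild-type H2O2 replicate 2, 415 without zuo1Δ H2O2 replicate 1 and 947 without zuo1Δ H2O2 replicate 2. Of the 12 named genes that passed, 7, 8, 9 and 12 kept their call in that order. In mRNA 14 genes passed, 7 higher and 7 lower, and DESeq2 called 637. The highest were YOR338W (3.32 ± 0.58, adjusted p = 0.0463), ZEO1 (2.96 ± 0.54, adjusted p = 0.0463), IGO1 (2.53 ± 0.40, adjusted p = 0.0463), QCR6 (2.40 ± 0.45, adjusted p = 0.0463) and PET20 (2.06 ± 0.38, adjusted p = 0.0463), and the lowest IMD2 (-4.55 ± 0.45, adjusted p = 0.000609), PDR15 (-2.95 ± 0.52, adjusted p = 0.0463), AIM17 (-2.54 ± 0.43, adjusted p = 0.0463), YPS6 (-2.48 ± 0.45, adjusted p = 0.0463) and PHO12 (-2.20 ± 0.41, adjusted p = 0.0463). Library size alone split the calls into 2 higher and 1 lower, with the median of all genes moved by 0.74. The count was 1 without wild-type H2O2 replicate 1, 1 without wild-type H2O2 replicate 2, 5 without zuo1Δ H2O2 replicate 1 and 0 without zuo1Δ H2O2 replicate 2. Among the 10 named genes that passed, 1, 1, 2 and 0 kept their call in that order. For efficiency no gene passed the edgeR test, while 710 had an unadjusted p under 0.05 and DESeq2 called 43.

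Whether the H2O2 response differed between genotypes was tested by the interaction, the zuo1Δ change minus the wild-type change. In footprints the calls among ribosome biogenesis and ribosomal protein genes were positive and those among general stress genes negative. YOR309C (3.35 ± 0.63, adjusted p = 0.0347), the rRNA processing factors TSR2 (2.11 ± 0.24, adjusted p = 0.00587) and FYV7 (1.85 ± 0.33, adjusted p = 0.0332), glutamate synthase GLT1 (2.06 ± 0.37, adjusted p = 0.0332) and the RNA polymerase III subunit RPC31 (1.66 ± 0.29, adjusted p = 0.0332) were highest (edgeR, n = 2 libraries in each of 4 groups). GID11 (-3.19 ± 0.68, adjusted p = 0.0499), proline oxidase PUT1 (-2.86 ± 0.54, adjusted p = 0.0347), CRG1 (-2.70 ± 0.51, adjusted p = 0.0347), SPI1 (-2.47 ± 0.46, adjusted p = 0.0347) and VMR1 (-2.32 ± 0.30, adjusted p = 0.00619) were lowest. Of 104 ribosome biogenesis genes, 4 rose and 0 fell (40 and 0 over the list alone). The median was 0.82 (camera adjusted p = 6.71e-24, and adjusted p = 0.468 with an estimated correlation). Among 136 cytosolic ribosomal protein genes, 11 rose and 0 fell (58 and 0 over the list alone). Their median was 0.56 (camera adjusted p = 5.8e-20, and adjusted p = 0.468 with an estimated correlation). For Msn2 and Msn4 general stress genes, 2 fell and 0 rose (24 and 1 over the list alone) of 42 measured. Their median was -1.91 (camera adjusted p = 2.75e-11, and adjusted p = 0.468 with an estimated correlation). Of the 31 Yap1 and Skn7 antioxidant genes measured, 0 fell and 0 rose (0 and 0 over the list alone). The median was -0.77 (camera adjusted p = 7.98e-06, and adjusted p = 0.564 with an estimated correlation). In all, 69 genes passed, 45 higher and 24 lower, and 20 passed without the doubted libraries. A fit of only the groups compared called 9 and kept 3 of the 10 named genes. The split with library size alone was 18 higher and 29 lower, at a shift of -0.08 in the median of all genes. The count was 123 without wild-type unstressed replicate 1, 3 without wild-type unstressed replicate 2, 5 without wild-type H2O2 replicate 1, 0 without wild-type H2O2 replicate 2, 2 without zuo1Δ unstressed replicate 1, 160 without zuo1Δ unstressed replicate 2, 20 without zuo1Δ H2O2 replicate 1 and 466 without zuo1Δ H2O2 replicate 2. Of the 10 named genes that passed, 8, 1, 2, 0, 2, 10, 3 and 10 kept their call in that order. In mRNA no gene passed the edgeR test, while 325 had an unadjusted p under 0.05 and DESeq2 called 4. For efficiency no gene passed the edgeR test, while 229 had an unadjusted p under 0.05 and DESeq2 called 0.

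The genotypes were compared after heat shock. In footprints more cytosolic chaperone and histone genes were lower than higher in zuo1Δ, and more mating and respiration genes were higher than lower. The Hsp70 copies SSA1 (-2.78 ± 0.35, adjusted p = 0.00131) and SSA2 (-2.49 ± 0.22, adjusted p = 0.000346), uncertain as near-identical genes, the Hsp90 HSP82 (-2.39 ± 0.41, adjusted p = 0.00665), VMR1 (-3.06 ± 0.30, adjusted p = 0.000367) and SIT1 (-2.40 ± 0.33, adjusted p = 0.00182) were lowest (n = 2 libraries per group, edgeR). HSP82 footprints stood at 7411 ± 1718 CPM (mean ± SD, n = 2) in heat-shocked wild type and 1414 ± 692 CPM in zuo1Δ. TDA6 (3.56 ± 0.82, adjusted p = 0.0248) and STP4 (2.97 ± 0.70, adjusted p = 0.0278), the glucose transporter HXT4 (2.76 ± 0.62, adjusted p = 0.0224) and YLR460C (2.56 ± 0.55, adjusted p = 0.0183) and GPG1 (2.19 ± 0.57, adjusted p = 0.0406) were highest. Cytosolic chaperones of the Hsf1 type (27 measured) had a median of -0.71 (camera adjusted p = 1.11e-06, and adjusted p = 0.34 with an estimated correlation). Among these, 12 fell and 0 rose (14 and 1 over the list alone). Of 12 mitochondrial chaperones, 3 fell and 0 rose (6 and 0 over the list alone). The median was -0.61 (camera adjusted p = 1.98e-05, and adjusted p = 0.306 with an estimated correlation). The chaperonin HSP60 (-1.59 ± 0.24, adjusted p = 0.00331) was among them. Among 25 endoplasmic reticulum folding genes, 4 fell and 0 rose (7 and 0 over the list alone). Their median was -0.16 (camera adjusted p = 0.038, and adjusted p = 0.309 with an estimated correlation). The camera adjusted p of this list became 0.0587 with library size alone, 0.0541 without wild-type heat replicate 1 and 0.1 without zuo1Δ heat replicate 2, within 0.0272 to 0.309 over all settings. They included KAR2 (-2.36 ± 0.26, adjusted p = 0.000507). For histone genes, 5 fell and 0 rose (7 and 0 over the list alone) of 10 measured. Their median was -1.08 (camera adjusted p = 6.95e-06, and adjusted p = 0.309 with an estimated correlation).

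Of the 16 mating and pheromone genes measured, 7 rose and 0 fell (11 and 0 over the list alone). The median was 0.94 (camera adjusted p = 2.11e-07, and adjusted p = 0.306 with an estimated correlation). The cell fusion gene FUS1 (1.80 ± 0.33, adjusted p = 0.00811) and the agglutinin subunit AGA1 (1.48 ± 0.37, adjusted p = 0.0347) were among them. A-cell genes (7 measured) had a median of 0.77 (camera adjusted p = 0.00103, and adjusted p = 0.306 with an estimated correlation). Among these, 3 rose and 0 fell (4 and 0 over the list alone). Of 48 respiration genes, 14 rose and 3 fell (23 and 3 over the list alone). The median was 0.50 (camera adjusted p = 1.66e-06, and adjusted p = 0.34 with an estimated correlation). The cytochrome subunits QCR9 (1.77 ± 0.33, adjusted p = 0.00986) and COX8 (1.40 ± 0.26, adjusted p = 0.00842) rose and aconitase ACO1 (-1.61 ± 0.23, adjusted p = 0.00247) fell. Partners of Zuo1 did not pass after heat, at SSZ1 (0.43 ± 0.15, adjusted p = 0.0977), SSB1 (0.32 ± 0.17, adjusted p = 0.3) and SSB2 (0.21 ± 0.15, adjusted p = 0.427). SSZ1 passed at 0.57 with library size alone and 0.41 without the doubted libraries. In all, 328 genes passed, 145 higher and 183 lower. Scaling by library size alone gave 291 higher and 107 lower and shifted the median of all genes by 0.14. The count was 87 without wild-type heat replicate 1, 72 without wild-type heat replicate 2, 231 without zuo1Δ heat replicate 1 and 93 without zuo1Δ heat replicate 2. Among the 17 named genes that passed, 9, 8, 15 and 7 kept their call in that order.

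In mRNA 1892 genes passed between the genotypes after heat, 826 higher and 1066 lower, but 0 passed without the doubted libraries together. The stress gene DDR48 (3.91 ± 0.92, adjusted p = 0.00974), the peroxidase GPX2 (3.78 ± 1.05, adjusted p = 0.0162) and NOP16 (3.72 ± 1.03, adjusted p = 0.0158), YHB1 (3.01 ± 0.59, adjusted p = 0.00813) and RPN4 (2.78 ± 0.39, adjusted p = 0.00813) were highest. PGK1 (-5.97 ± 1.22, adjusted p = 0.00813), SML1 (-5.70 ± 1.11, adjusted p = 0.00813), CAR2 (-5.27 ± 1.04, adjusted p = 0.00813), PMP2 (-5.23 ± 1.10, adjusted p = 0.00837) and PNS1 (-4.88 ± 1.04, adjusted p = 0.00843) were lowest. Among 27 glycolysis and fermentation genes, 19 fell and 0 rose (19 and 0 over the list alone). Their median was -2.30 (camera adjusted p = 4.91e-07, and adjusted p = 0.638 with an estimated correlation). Library size alone split the calls into 2940 higher and 181 lower, with the median of all genes moved by 1.51. The count was 0 without wild-type heat replicate 1, 1407 without wild-type heat replicate 2, 1010 without zuo1Δ heat replicate 1 and 0 without zuo1Δ heat replicate 2. Of the 10 named genes that passed, 0, 9, 8 and 0 kept their call in that order. Translational efficiency passed for 1474 genes, 788 higher and 686 lower, led by SNA2 (5.57 ± 1.05, adjusted p = 0.00885), CAR2 (4.95 ± 1.06, adjusted p = 0.00885), PGK1 (4.89 ± 1.10, adjusted p = 0.00922), SML1 (4.78 ± 1.11, adjusted p = 0.0102) and VRG4 (4.56 ± 0.91, adjusted p = 0.00885). The lowest were DDR48 (-4.25 ± 1.16, adjusted p = 0.0154), YLH47 (-3.74 ± 0.66, adjusted p = 0.00885), GCN4 (-3.55 ± 0.80, adjusted p = 0.00938), NOP16 (-3.48 ± 1.08, adjusted p = 0.0246) and VMR1 (-3.25 ± 0.53, adjusted p = 0.00885). Library size alone gave 185 higher and 2330 lower for efficiency, at a shift of -1.31 in the median of all genes. For cytosolic ribosomal protein genes, 44 rose and 1 fell (46 and 2 over the list alone) of 136 measured. Their median was 0.73 (-0.71 with library size alone, the opposite direction) (camera adjusted p = 1.18e-05, and adjusted p = 0.662 with an estimated correlation). The efficiency model had a biological coefficient of variation of 0.265, against 0.318 for mRNA, so its test may understate mRNA noise. PGK1, CAR2, SML1, DDR48 and NOP16 also led in mRNA with the opposite sign. Their efficiency calls were not told apart from mRNA differences, which no longer passed without the doubted libraries. Counts without single libraries are given below as a range.

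The interaction of heat and genotype tested whether the heat response differed. In footprints the calls among phosphate genes were positive, and those among histones and cytosolic chaperones negative. PHO5 (3.78 ± 0.38, adjusted p = 0.000794), the rRNA processing factor TSR2 (1.82 ± 0.24, adjusted p = 0.00914), isopropylmalate isomerase LEU1 (1.63 ± 0.21, adjusted p = 0.00914), the RNA polymerase subunit RPC10 (1.63 ± 0.27, adjusted p = 0.0241) and flavohaemoglobin YHB1 (1.63 ± 0.28, adjusted p = 0.0241) were highest (edgeR, n = 2 libraries in each of 4 groups). GSC2 (-2.90 ± 0.25, adjusted p = 0.000346), VMR1 (-2.56 ± 0.38, adjusted p = 0.0185), HTA2 (-2.31 ± 0.42, adjusted p = 0.0256), SSA1 (-2.31 ± 0.47, adjusted p = 0.0355) and SIT1 (-2.26 ± 0.45, adjusted p = 0.0347) were lowest. Of the 15 genes of the phosphate regulon measured, 5 rose and 0 fell (13 and 0 over the list alone). The median was 1.24 (camera adjusted p = 5.19e-14, and adjusted p = 0.011 with an estimated correlation). Histone genes (10 measured) had a median of -1.48 (camera adjusted p = 2.68e-08, and adjusted p = 0.268 with an estimated correlation). Among these, 4 fell and 0 rose (9 and 0 over the list alone). Of 27 cytosolic chaperones of the Hsf1 type, 5 fell and 0 rose (10 and 1 over the list alone). The median was -0.60 (camera adjusted p = 0.000842, and adjusted p = 0.649 with an estimated correlation). Among 136 cytosolic ribosomal protein genes, 5 rose and 0 fell (32 and 1 over the list alone). Their median was 0.41 (camera adjusted p = 1.4e-15, and adjusted p = 0.456 with an estimated correlation). For a-cell genes, 1 rose and 0 fell (4 and 0 over the list alone) of 7 measured. Their median was 1.00 (camera adjusted p = 1.21e-05, and adjusted p = 0.196 with an estimated correlation). Of the 16 mating and pheromone genes measured, 2 rose and 0 fell (4 and 0 over the list alone). The median was 0.95 (camera adjusted p = 4.09e-06, and adjusted p = 0.268 with an estimated correlation).

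For the heat interaction 52 genes passed in footprints, 31 higher and 21 lower, and 102 passed without the doubted libraries. The split with library size alone was 21 higher and 28 lower, at a shift of -0.10 in the median of all genes. The count was 11 without wild-type unstressed replicate 1, 3 without wild-type unstressed replicate 2, 7 without wild-type heat replicate 1, 2 without wild-type heat replicate 2, 7 without zuo1Δ unstressed replicate 1, 34 without zuo1Δ unstressed replicate 2, 48 without zuo1Δ heat replicate 1 and 22 without zuo1Δ heat replicate 2. Among the 10 named genes that passed, 6, 3, 5, 2, 5, 8, 7 and 6 kept their call in that order. In mRNA no gene passed the edgeR test, while 891 had an unadjusted p under 0.05 and DESeq2 called 74, and leaving out single libraries gave 477 without zuo1Δ unstressed replicate 2 and 0 without each other library. For efficiency no gene passed the edgeR test, while 745 had an unadjusted p under 0.05 and DESeq2 called 12, and leaving out single libraries gave 422 without mRNA wild-type unstressed replicate 1, 343 without mRNA zuo1Δ unstressed replicate 2 and 0 without each other library.

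**Figure D2:**
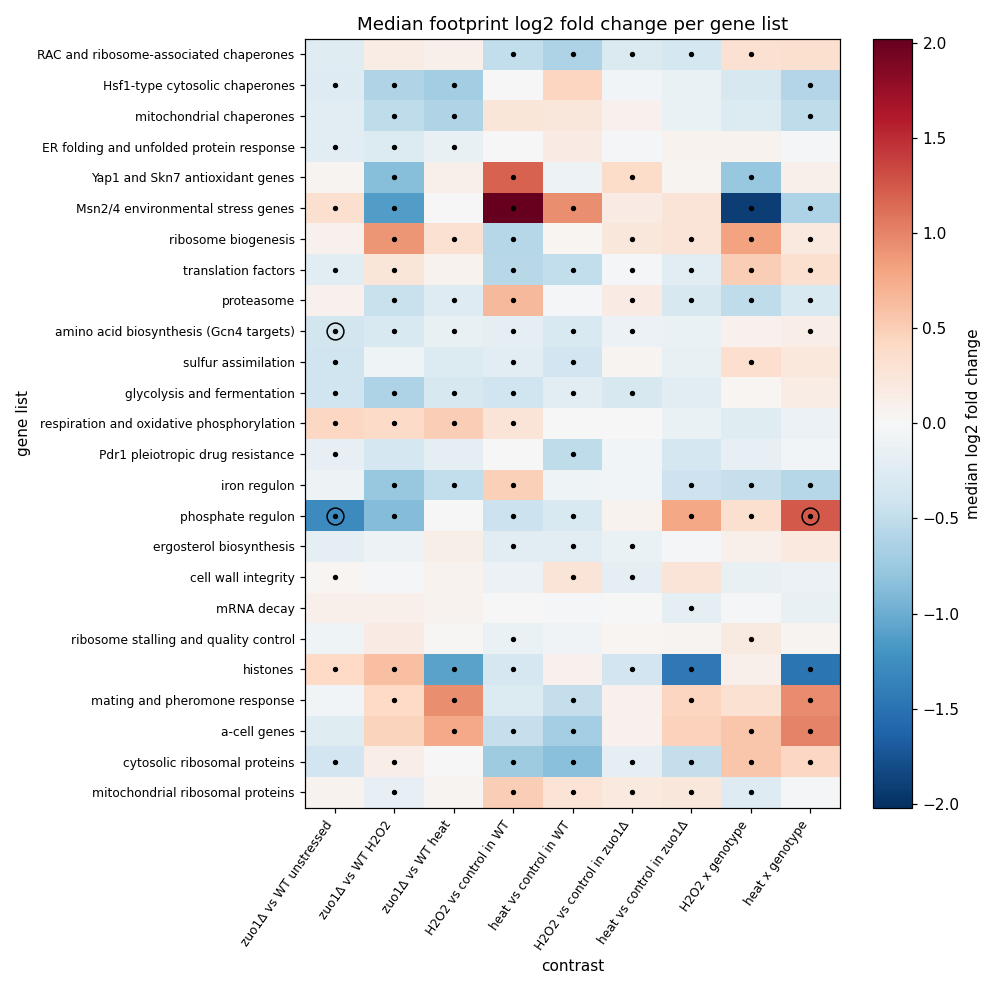
Median footprint log2 fold change of each tested gene list (y axis) in the 9 contrasts (x axis), as a colour scale that is symmetric about 0. A dot marks a camera adjusted p under 0.05 with the preset correlation and a ring the same with an estimated correlation.

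**Figure D3:**
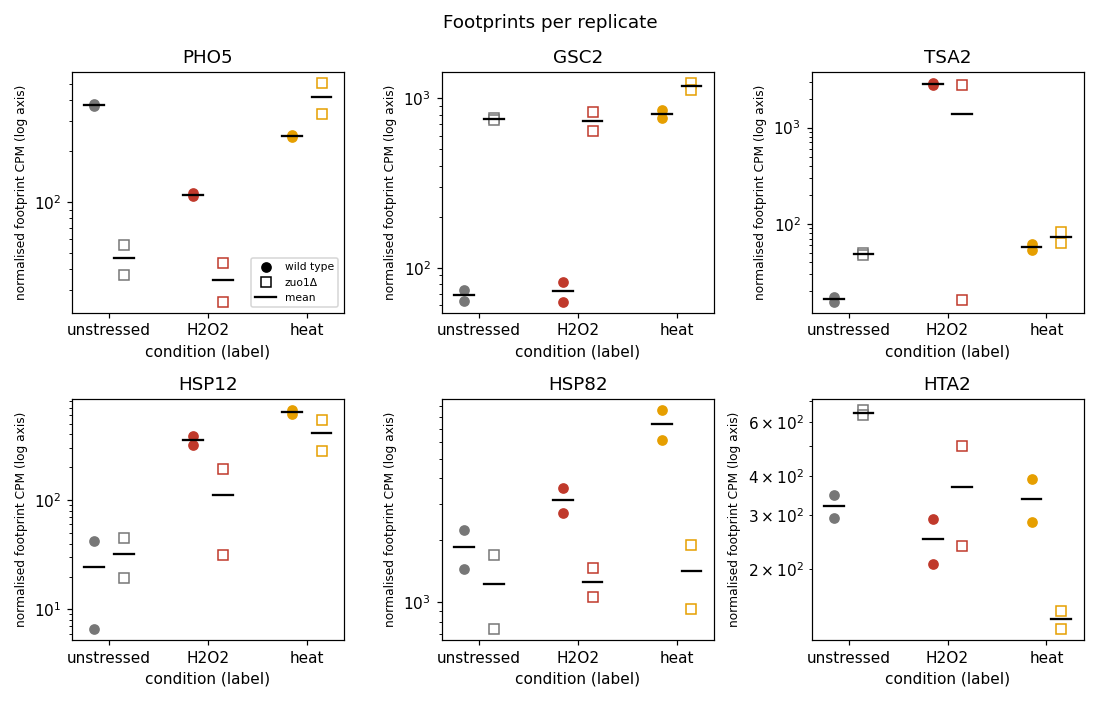
Normalised footprint CPM (log axis) of PHO5, GSC2, TSA2, HSP12, HSP82 and HTA2 in each of the 12 footprint libraries. Points are single replicates and bars the mean of the 2 replicates of a group, with wild type and zuo1Δ side by side in each condition.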

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

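The marker, label, composition and depth tests of the libraries were chosen only after the results they bear on were seen, while the slope test and both tests of genes at 0 were set beforehand. The H2O2 interaction test called 69 footprint genes. The zuo1Δ change exceeded the wild-type change for YOR309C (3.35, adjusted p = 0.0347), TSR2 (2.11, adjusted p = 0.00587), FYV7 (1.85, adjusted p = 0.0332), GLT1 (2.06, adjusted p = 0.0332) and RPC31 (1.66, adjusted p = 0.0332), and lay below it for GID11 (-3.19, adjusted p = 0.0499), PUT1 (-2.86, adjusted p = 0.0347), CRG1 (-2.70, adjusted p = 0.0347), SPI1 (-2.47, adjusted p = 0.0347) and VMR1 (-2.32, adjusted p = 0.00619). Camera with the preset correlation picked these lists, but none with an estimated correlation (second adjusted p): ribosome biogenesis (0.82, camera adjusted p = 6.71e-24 and 0.468), cytosolic ribosomal proteins (0.56, camera adjusted p = 5.8e-20 and 0.468), Msn2/4 environmental stress genes (-1.91, camera adjusted p = 2.75e-11 and 0.468) and Yap1 and Skn7 antioxidant genes (-0.77, camera adjusted p = 7.98e-06 and 0.564). 1 of the 2 zuo1Δ H2O2 footprint libraries is doubted (H2O2 markers 0.11 against 1.60), which may itself give these differences. A fit of only the groups compared called 9.

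For heat the interaction test found 52 footprint genes whose response differed between genotypes. It lay above the wild-type response for PHO5 (3.78, adjusted p = 0.000794), TSR2 (1.82, adjusted p = 0.00914), LEU1 (1.63, adjusted p = 0.00914), RPC10 (1.63, adjusted p = 0.0241) and YHB1 (1.63, adjusted p = 0.0241), and below it for GSC2 (-2.90, adjusted p = 0.000346), VMR1 (-2.56, adjusted p = 0.0185), HTA2 (-2.31, adjusted p = 0.0256), SSA1 (-2.31, adjusted p = 0.0355) and SIT1 (-2.26, adjusted p = 0.0347). The preset correlation picked these lists, and an estimated correlation only the first: phosphate regulon (1.24, camera adjusted p = 5.19e-14 and 0.011), histones (-1.48, camera adjusted p = 2.68e-08 and 0.268), Hsf1-type cytosolic chaperones (-0.60, camera adjusted p = 0.000842 and 0.649), cytosolic ribosomal proteins (0.41, camera adjusted p = 1.4e-15 and 0.456), a-cell genes (1.00, camera adjusted p = 1.21e-05 and 0.196) and mating and pheromone response (0.95, camera adjusted p = 4.09e-06 and 0.268). Genes listed in only 1 genotype were fitted within it, and those past the threshold in footprints were named after their values were seen. The risers were the glucoamylase SGA1 after H2O2 in wild type (2.52, adjusted p = 0.0239), and LDS2 (4.08, adjusted p = 0.0316) and the cell wall protein PIR3 (2.75, adjusted p = 0.0235) after heat in zuo1Δ. In wild type ZUO1 fell after H2O2 (-0.86, adjusted p = 0.000119) and heat (-0.42, adjusted p = 0.0132), both less by library totals. CIS1 fell after heat there (-1.76, adjusted p = 0.044).

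In 3 stressed zuo1Δ libraries the markers of the label's stress stood no higher than in the highest unstressed library. In mRNA, the library labelled heat replicate 1 exceeded the library labelled H2O2 replicate 2 by 0.643 on the H2O2 markers and fell below it by 0.501 on the heat markers, against gaps of up to 0.893 and 0.247 between replicates of wild type or unstressed zuo1Δ. The H2O2 part lay within that spread and the heat part beyond it, so an exchange of these 2 libraries stays open. An uneven response of correctly labelled cultures stays open too, since the H2O2-labelled library differed from its partner by 0.824 on the heat markers, beyond that spread, and by -0.861 on the H2O2 markers, within it. In footprints, the library labelled H2O2 replicate 1 lay at -0.564 relative to the higher unstressed zuo1Δ library, whose partner lay 0.676 away, as cells without H2O2 would. A correctly labelled culture that did not respond gives the same value, with -1.49 relative to its partner, and cannot be told apart from it with these libraries.

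The mRNA libraries spread along 1 axis that also parted the genotypes, the first principal component with 60.05% of the variance. The widest gap between replicates was 51.8, in unstressed zuo1Δ, or 0.821 of the genotype difference of 63.1, so composition that varies from library to library within a group is a candidate explanation. The deeper library had the larger share of counts in its 50 highest genes in 5 of 6 groups (exact two-sided sign test, p = 0.219), which leaves depth open. A genotype difference in transcripts that carried over to footprints also stays open, since the slope of the footprint on the mRNA change across genes was 0.196 (bootstrap interval 0.175 to 0.216, genes not being independent replicates).

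A further pattern was 141 genes at 0 in all 12 libraries of 1 genotype, ZUO1 among them. Of the other 140, 126 (90.0%) lay in the lowest 10% of footprint levels where listed, so an authors' filter per genotype is a candidate explanation. Loss of expression alone is argued against, since 0 genes were at 0 in part of a genotype. It stays open for 18 of 140, expected at 10 or more footprints in the shallowest library not listing them (median of all, 3.57).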

How the results depend on the processing

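Leaving out the doubted libraries, keeping genes at 0 in 1 genotype and the voom fit were chosen only after the results were seen. Of 197 gene calls named in the text, 68 stayed past the threshold in every setting run, as did 3 of 56 list calls, and no gene call or list test that passed in the reported fit turned direction. TSA2 after H2O2 in zuo1Δ, not called there, passed in both directions, at 5.85 without zuo1Δ H2O2 replicate 1 and -1.61 without replicate 2. The medians of the Pdr1 and endoplasmic reticulum lists in unstressed footprints, of ergosterol genes in heat-shocked zuo1Δ footprints and of ribosomal proteins for efficiency in heat, and the value of SSZ1, changed sign with library size alone. An estimated correlation ended 53 list calls and kept 3. Counts without a stated change lay within 1.5 times the reported ones. With 2 libraries per group changes may be missed, and recovery and calls of unchanged genes were measured only for simulated spread.

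The counts that moved by over 1.5 times were as follows, and the cause was not tested except where fewer libraries were fitted. DESeq2 gave mRNA 610 (genotype unstressed), 637 (genotype in H2O2), 596 (H2O2 in wild type), 646 (heat in wild type), 87 (H2O2 in zuo1Δ), 66 (heat in zuo1Δ), 4 (H2O2 interaction), 74 (heat interaction), footprints 27 (H2O2 in zuo1Δ), 327 (H2O2 interaction), 155 (heat interaction) and efficiency 133 (genotype unstressed), 43 (genotype in H2O2), 20 (H2O2 in wild type), 18 (heat in wild type), 12 (heat interaction). Library size alone gave mRNA 3022 (genotype unstressed), 3 (genotype in H2O2), 3121 (genotype in heat), 1581 (H2O2 in wild type), 53 (heat in wild type), 2 (heat in zuo1Δ), footprints 488 (genotype unstressed), 819 (heat in wild type) and efficiency 826 (genotype unstressed), 2515 (genotype in heat), 1 (heat in wild type). RLE factors gave mRNA 20 (heat in wild type). Without the low-count filter no count moved by as much. A fit of only the groups compared gave mRNA 0 (genotype unstressed), 941 (genotype in H2O2), 318 (H2O2 in wild type), 209 (heat in wild type), 1 (H2O2 in zuo1Δ), 4 (heat in zuo1Δ), footprints 385 (heat in zuo1Δ), 9 (H2O2 interaction) and efficiency 0 (genotype unstressed), 1 (genotype in H2O2), 2 (heat in wild type). The replicate block gave mRNA 472 (genotype unstressed), 633 (genotype in H2O2), 397 (H2O2 in wild type), 119 (heat in wild type), 2 (heat in zuo1Δ), footprints 216 (H2O2 interaction), 85 (heat interaction) and efficiency 8 (genotype unstressed), 2 (heat in wild type). Replicate numbers were not taken to pair the cultures, since of 30 pairs of groups in the same assay 15 had replicate differences correlated above 0.1 across genes, from -0.327 to 0.783. The 12 pairs without zuo1Δ H2O2 or zuo1Δ heat, chosen after the values were seen, ran from 0.111, so pairing there stays open. Without the doubted libraries the counts were mRNA 3 (genotype unstressed), 0 (genotype in H2O2), 0 (genotype in heat), 34 (H2O2 in wild type), 9 (heat in wild type), 5 (H2O2 in zuo1Δ), footprints 415 (genotype in H2O2), 184 (H2O2 in zuo1Δ), 20 (H2O2 interaction), 102 (heat interaction) and efficiency 0 (genotype unstressed). Keeping genes at 0 in 1 genotype gave mRNA 341 (genotype unstressed), 279 (genotype in H2O2), 22 (heat in wild type). The voom fit gave mRNA 3 (genotype unstressed), 7 (genotype in H2O2), 14 (H2O2 in wild type), 4 (heat in wild type).

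Leaving out 1 library at a time leaves an arm with 1 sample, which is then assumed to vary like the other groups. The mRNA counts then ran from 4 to 515 (genotype unstressed), 0 to 5 (genotype in H2O2), 0 to 1407 (genotype in heat), 0 to 67 (H2O2 in wild type), 0 to 663 (heat in wild type), 0 to 4 (H2O2 in zuo1Δ), 0 to 0 (heat in zuo1Δ), 0 to 0 (H2O2 interaction), 0 to 477 (heat interaction). The footprint counts ran from 71 to 1.0e+02 (genotype unstressed), 157 to 947 (genotype in H2O2), 72 to 231 (genotype in heat), 233 to 654 (H2O2 in wild type), 133 to 239 (heat in wild type), 0 to 184 (H2O2 in zuo1Δ), 142 to 369 (heat in zuo1Δ), 0 to 466 (H2O2 interaction), 2 to 48 (heat interaction), the highest of the first rounded to 2 digits. The efficiency counts ran from 0 to 399 (genotype unstressed), 0 to 1 (genotype in H2O2), 407 to 1461 (genotype in heat), 0 to 1 (H2O2 in wild type), 0 to 309 (heat in wild type), 0 to 0 (H2O2 in zuo1Δ), 0 to 47 (heat in zuo1Δ), 0 to 0 (H2O2 interaction), 0 to 422 (heat interaction). Library size alone moved the median efficiency of all genes by -1.09 (genotype unstressed), -0.49 (genotype in H2O2), -0.90 (H2O2 in wild type), -0.29 (H2O2 in zuo1Δ), -0.27 (heat in zuo1Δ), 0.60 (H2O2 interaction) and -0.21 (heat interaction). It moved the median mRNA interaction with H2O2 by -0.77, mRNA heat in zuo1Δ by 0.45 and footprint H2O2 in zuo1Δ by 0.13. RLE factors moved efficiency by 0.10 (genotype in H2O2) and 0.10 (genotype in heat).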

Other observations

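The Crz1 test and the test of the phosphate regulon across stresses were chosen only after the results they follow were seen, while the share of genotype effects kept in heat was set beforehand. Genes that make ergosterol, the main yeast sterol, in heat-shocked zuo1Δ footprints (28 measured) had a median of -0.02 (0.14 with library size alone, the opposite direction) (camera adjusted p = 0.672, and adjusted p = 0.878 with an estimated correlation). Among these, 2 rose and 2 fell (3 and 3 over the list alone). The sterol-pathway cytochrome CYB5 (1.21 ± 0.21, adjusted p = 0.00567) rose and squalene synthase ERG9 (-0.71 ± 0.15, adjusted p = 0.0139) fell. Across genes, which are not independent replicates, footprint and mRNA changes correlated at r = 0.319, 0.494, 0.123, 0.603, 0.501, 0.4 and 0.344 for the genotype differences unstressed, in H2O2 and in heat, H2O2 and heat in wild type, and H2O2 and heat in zuo1Δ.

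A hypothesis is that calcineurin signalling through Crz1, which induces GSC2, ENA1, PHO89 and CMK2, may be raised in unstressed zuo1Δ cells. The 12 other targets tested had a median footprint log2 fold change of 0.591, and 10 were positive. Of the 12, 2 rose over all genes and 8 adjusted over the list alone. Camera gave p = 1.04e-05 with the preset correlation and p = 0.0607 with an estimated correlation, so the test leaves the hypothesis open. In mRNA the median was -0.03.

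A further hypothesis is that the genotype effect on footprints may not depend on the stress. For the phosphate regulon this is argued against, since its median difference of -1.29 without stress met -0.01 in heat, in other libraries, and an interaction with heat of 1.24 (camera adjusted p = 0.011 with an estimated correlation). Of 244 genes that passed without stress, 77.9% had the same sign in heat, from other libraries. In both, 25 genes were called higher and 35 lower, against 2.58 and 5.57 for independent calls. Calls from 1 fit share gene variances, so the overlap decides nothing. The share lay between the 2 limits set for the test. For genes outside that list the hypothesis stays open, though 52 of all genes passed the heat interaction. After H2O2, where 1 zuo1Δ library is doubted, the share was 82%.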
